A study of Mus musculus with 2 samples.

How the data were processed

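H3K27me3, the trimethyl mark that Polycomb repressive complex 2 places on lysine 27 of histone H3, was measured by ChIP-seq (chromatin immunoprecipitation and sequencing) in hindbrain tissue of B6N mice on postnatal day 0. There was 1 group with 2 biological replicates, each a pool of male and female animals per the labels. The pool of replicate 1 held 15 mice, and the number of mice in the pool of replicate 2 is not given in the labels. Replicates took their numbers from the labels.

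The authors deposited 4 peak lists in narrowPeak format on the mm10 assembly: a list for each replicate, a list called on both replicates together (pooled) and a list of replicated peaks. Per the text files deposited with the libraries, the reads were aligned to mm10 and a control alignment entered peak calling. The aligner, the peak caller and their settings are not given in the sources used here. Every replicated peak was also a peak of the pooled list, but the rule that selected them is not given in the sources used here. The control library and the read counts of the libraries were not analysed here, so the sequencing depth behind each list is unknown and no limit from counts is given.

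Each peak of the deposited lists carries a score from the authors, with 1000 as its highest value in the pooled list. Replicated peaks carry the score and other values of the same peaks in the pooled list. The signal value of each peak, per the file format named in the deposited text, is its enrichment over the control as the authors computed it. The deposited −log10 p and −log10 q values (p-value and q-value) of each peak are also those of the authors. The lowest −log10 p was 2.02 in the pooled list and 2.04 in the replicate 1 list, and the lowest −log10 q there was 0.165 and 0.0315, so the lists included peaks far from a usual q threshold. All peak values are the authors' own. They were used to rank or filter peaks within a list and to correlate the replicate lists across replicated peaks. Enrichment values were not compared in size between lists.

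Peaks were compared with the GENCODE M21 annotation of the same assembly (GRCm38), and all peaks lay inside its chromosome lengths. Of 21938 protein-coding gene models on the autosomes, X and Y, the longest model of each symbol was kept, which left 21911 genes. A TSS window was the 5′ end of the gene model with 2.5 kb on either side, and a gene was counted as having a TSS peak when at least 1 bp of its window lay under a peak of the replicated list. The share of the window, or of the gene body, under peaks was the measure of extent. Domains were replicated peaks merged across gaps of up to 3 kb. The CpG observed/expected ratio was computed from the genome sequence. Coordinates are 1-based.

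A total of 27 gene lists, the tests, the rule for named genes and the alternatives, except those named in the closing section as chosen later, were fixed before the data were examined. Each list was set against all other genes with a two-sided Fisher's exact test, adjusted over the 27 lists by the Benjamini-Hochberg method with a threshold of 0.05, and against 10000 random lists matched on the decile of CpG observed/expected. Differences in covered share between gene lists were tested with two-sided permutation tests of 100000 resamples, with 95% bootstrap intervals over genes (10000 resamples). Shares of genes have Wilson 95% intervals. Overlap of the replicate lists was set against 1000 circular shifts of one list within each chromosome, and the annotation of peaks against 100 such shifts. These p-values describe gene sets and intervals in these libraries: genes are not independent replicates, neighbouring genes can share a domain, and several lists share members. With 1 group there was no comparison between conditions.

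Per list, the named genes were up to 4 members with a TSS peak and the largest covered share of the window, and up to 2 members without a peak, first by alphabet. Every Hox gene and every gene under the 10 longest domains could be named, as could list members whose status differed between the replicate lists, where there were at most 5 in a list. Genes named outside this rule were chosen after their values were seen, and the text says so.

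Alternatives were stricter peak thresholds (−log10 q of at least 2, −log10 p of at least 5), each replicate list alone, each replicate list reduced by −log10 p to as many peaks as the replicated list, the pooled list, TSS windows of 1 kb and 5 kb on either side, other minimum overlaps, other merge distances (1 kb and 10 kb) and other backgrounds. The list test was tested on simulated data: 3 of 3 lists with planted peaks were called, and 5 of 2700 lists were called after TSS calls were shuffled over the 21911 genes. The permutation test gave a p below 0.05 in 10 of 200 simulated comparisons of independent normal values without a difference. These simulations treated genes as independent, so they give no error rate for neighbouring genes that share a domain. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.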

Results

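H3K27me3 ChIP-seq of newborn mouse hindbrain was represented by 2 biological replicates of 1 group, and the labels name no second condition. The replicate 1 list held 42789 peaks over 13.2 Mb, and the replicate 2 list held 42727 peaks over 14.9 Mb. The pooled list held 62553 peaks over 23.5 Mb, of which 12087, covering 10.2 Mb, made up the replicated list. Peaks were short, with median widths of 240, 247 and 255 bp in the replicate 1, replicate 2 and pooled lists and of 585 bp in the replicated list. The shortest peaks of the replicate 1, replicate 2 and pooled lists had 200, 195 and 195 bp, so those medians lay near the lowest width called. Long marked stretches were split into many calls: the span of the Hoxa cluster held 53 replicated peaks. The lists held no peak on chromosome Y.

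The first question was how far both replicates marked the same regions. They shared 4.59 Mb of peak bases, a Jaccard index of 0.195 against a mean of 0.00288 and a highest value of 0.00738 over 1000 shifts (permutation p = 0.001, one-sided, the smallest that this number of shifts can give). Of the replicate 1 peaks 32.9% overlapped a replicate 2 peak, and 30.4% of the replicate 2 peaks overlapped a replicate 1 peak, against a mean of 1.07% of replicate 1 peaks under shifts. At −log10 q of at least 2 the overlapped share of replicate 1 peaks was 63.1%, but there 6574 replicate 1 peaks faced 13921 replicate 2 peaks, and the Jaccard index was 0.253. Of the pooled peaks 19.3% were in the replicated list, from 0.927% in the lowest quartile of pooled peaks by score to 62.3% in the highest. Pooled peaks outside the replicated list had a median width of 235 bp. Of the replicated peaks, 10359 (85.7%) touched peaks of both replicate lists, and across these peaks the signal values of the replicates had a Pearson r of 0.49 and a Spearman rho of 0.41, where peaks are not independent replicates.

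TSS windows of 1982 of 21911 protein-coding genes (9.05%) carried a replicated peak. The full lists of replicates 1 and 2 marked 3447 and 3451 genes, of which 2341 were marked in both, and the pooled list marked 4287. Below, a gene is called without a peak by the replicated list, and some such genes carried peaks in other lists. Covered shares are also those of the replicated list unless another list is named. Its peaks have the extent called on both replicates together. Of these 12087 peaks, 6635 were covered to at least 50% by each replicate list. Forebrain regulators had a mean share of 74.1% there, against 51.3% and 65.2% in the lists of replicates 1 and 2. For Fezf2 the shares were 99.3%, 56.5% and 92.1%. Genes marked by one replicate alone numbered 1106 for replicate 1 and 1110 for replicate 2.

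Most regulators of forebrain, hindbrain, spinal cord, mesoderm and endoderm development carried H3K27me3 at their TSS in this tissue. All 22 regulators of spinal cord and motor neuron identity had a peak, among them Mnx1, a motor neuron homeobox factor, with 100% of its window covered, and Nkx2-9, Foxn4 and Prdm12 with 97.7%, 95.1% and 94.2%. Of 34 forebrain regulators 32 had a peak, among them Six3, needed for the anterior forebrain and eye, with 100% covered, Fezf2, which specifies subcerebral projection neurons, with 99.3%, Sim1 with 99.2% and Vax2 with 97.0%. Of 46 mesoderm regulators 42 had a peak, with 100% coverage at Foxf1, Pax9, Hand2 and Six2. Among 29 endoderm and epithelial regulators 21 had a peak, among them Cdx2, an intestinal homeobox factor (100%), Neurog3 (98.6%), the pancreatic factor Pdx1 (96.9%) and Foxa1 (96.5%).

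Of the 32 hindbrain and cerebellar regulators 28 had a peak. Pax7 (93.2% covered), Lmx1a, a roof plate factor (90.2%), Ptf1a, which specifies inhibitory cerebellar neurons (88.7%) and Lmx1b (85.8%) led this list. The members without a peak were Meis1, Meis2, Zic2 and Zic4. Meis proteins are cofactors of Hox proteins, and Zic factors act in cerebellar granule cells. Zic2 here, and Myf6, Myog and Zic1 below, were named after their values were seen. Of the hindbrain and cerebellar members without a peak, only Meis1 had none in any of the 4 lists. Zic2 had a peak in both replicate lists (9.52% and 4.18% of its window) and the pooled list (11.8%), and Meis2 and Zic4 had one in the replicate 2 list (5.94% and 10.04%) and the pooled list (10.5% and 15.04%), but not in the replicate 1 list. The forebrain regulators without a peak were Hesx1 and Pou3f4. The mesoderm regulators without a peak were Mesp2, marked in the replicate 2 list, and the muscle regulatory factors Myf5, Myf6 and Myog. Among the endoderm and epithelial regulators, Ehf and Elf3 were 2 of the 8 without a peak, and Elf3 was marked in the replicate 1 list. Other genes carried TSS peaks at 8.87 to 8.96% in these 5 comparisons, and each list differed from other genes (adjusted Fisher's exact p from 1.52e-38 to 6.60e-16). The highest share among CpG-matched random lists was 41.2% for the forebrain list and 37.9% for the endoderm list.

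Homeobox and other transcription factor families were marked in whole or in large part. All 15 Hox genes of paralog groups 1 to 5 and all 24 of groups 6 to 13 had a TSS peak, as did all 9 Pax genes and all 12 LIM homeobox genes. In the Nkx family 13 of 14 had a peak, all but Nkx6-3, among the Irx, Dlx and sine oculis-related (Six3 and relatives) families 16 of 18, all but Irx5 and Six4 (18 of 18 in the replicate 2 and pooled lists), and in the Gata family 5 of 6, all but Gata1, the erythroid factor on chromosome X. The T-box family had 12 of 17, with Tbx15 (94.8%) and Tbx5 (94.1%) among the most covered, and the Fox family had 28 of 44, with Foxe3 at 97.2%. The Sox family was split, with a peak at 10 of 19. Sox14 (98.9%), Sox17 (83.4%), Sox7 (69.5%) and Sox1 (68.3%) were covered, whereas Sox11 and Sox12, widely expressed in developing neurons, had no peak. Of secreted signals, 17 of 19 Wnt ligands, 8 of 22 Fgf ligands and 10 of 21 Bmp and Gdf ligands had a peak, and the Wnt ligands without a peak were Wnt5a and Wnt8a. Irx5 was marked in both replicate lists (23.3% and 8.34% of its window), Wnt5a in the replicate 2 list (9.26%), Wnt8a in the replicate 1 list (4.74%), and all 3 in the pooled list. These families all lay above other genes, with adjusted Fisher's exact p of at most 0.000599. The Fgf ligands (36.4%) lay below the highest CpG-matched random list (40.9%), and the Gata family equalled it (83.3%).

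Lists of neuronal, glial, and blood and endothelial genes were also marked more often than other genes. Of 26 neuronal genes 7 had a peak, and the most covered encode transmitter transporters and an enzyme: Slc6a5, the glycine transporter (79.9%), Slc32a1, the vesicular inhibitory amino acid transporter (64.1%), Slc17a7, a vesicular glutamate transporter (35.9%), and Gad2 (34.9%). Of 26 glial genes 9 had a peak, with Olig1 (95.9%) and Olig2 (82.6%), the oligodendrocyte lineage factors, in front, while Aldh1l1 and Apoe had none, although Apoe was marked in the replicate 2 list. Of 26 blood and endothelial genes 7 had a peak, among them the blood stem cell factor Tal1 (71.3%), Sox18 (66.8%), Pax5 (65.7%) and Ikzf1 (59.1%). The adjusted Fisher's exact p was 0.00849 for the neuronal and blood lists and 0.000425 for the glial list. Their shares were not above every CpG-matched random list: 26.9% of neuronal genes against a highest value of 42.3%, 26.9% of blood and endothelial genes against 30.8%, and 34.6% of glial genes against the same 34.6%. The neuronal call was lost on the replicate 1 list alone (adjusted exact p = 0.177), and the blood call on the replicate 2 list alone (adjusted exact p = 0.0572) and on the pooled list (adjusted exact p = 0.084).

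Lower than other genes were the olfactory receptors (4 of 1092, adjusted Fisher's exact p = 1.52e-38), the clustered protocadherins (0 of 56, adjusted exact p = 0.0102, Wilson upper limit 6.42%) and the ribosomal protein genes (1 of 76, adjusted exact p = 0.0157). Clustered protocadherins such as Pcdha1, Pcdha11 and Pcdhb1 lie close together on chromosome 18, so their p and interval treat neighbours as independent. The lists of replicates 1 and 2 marked 22 and 14 olfactory receptors, 1 and 0 clustered protocadherins, and 3 and 5 ribosomal protein genes. The single ribosomal protein gene with a peak in the replicated list, Rpl3l, is a form restricted to muscle. The ribosomal call was lost with a window of 1 kb (adjusted exact p = 0.0732). Olfactory receptor windows are poor in CpG: lists matched on CpG reached 0.733% at the median. The receptors, at 0.366%, lay at percentile 5.09 of these lists, and their call was lost among genes above the median CpG ratio. Clustered protocadherins and ribosomal protein genes lay at percentiles 0.015 and 0.01 of their matched lists. The replicated list did not pass the test for housekeeping genes (0 of 30, adjusted exact p = 0.116, Wilson upper limit 11.4%), non-neural terminal genes (2 of 32, Ckm and Acta1, adjusted exact p = 1) or cell cycle inhibitors (2 of 7, adjusted exact p = 0.131). The 2 marked cell cycle inhibitors were the neighbours Cdkn2a (96.3% covered) and Cdkn2b (84.3%). Housekeeping genes passed as lower on the replicate 2 list alone (adjusted exact p = 0.0119) and on the pooled list (adjusted exact p = 0.0224). Cell cycle inhibitors passed as higher on the replicate 1 list alone (adjusted exact p = 0.0161), with its best peaks (adjusted exact p = 0.0165) and with a window of 5 kb (adjusted exact p = 0.03). In all, 21 lists lay above other genes, 3 below and 3 neither.

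**Figure D1:**
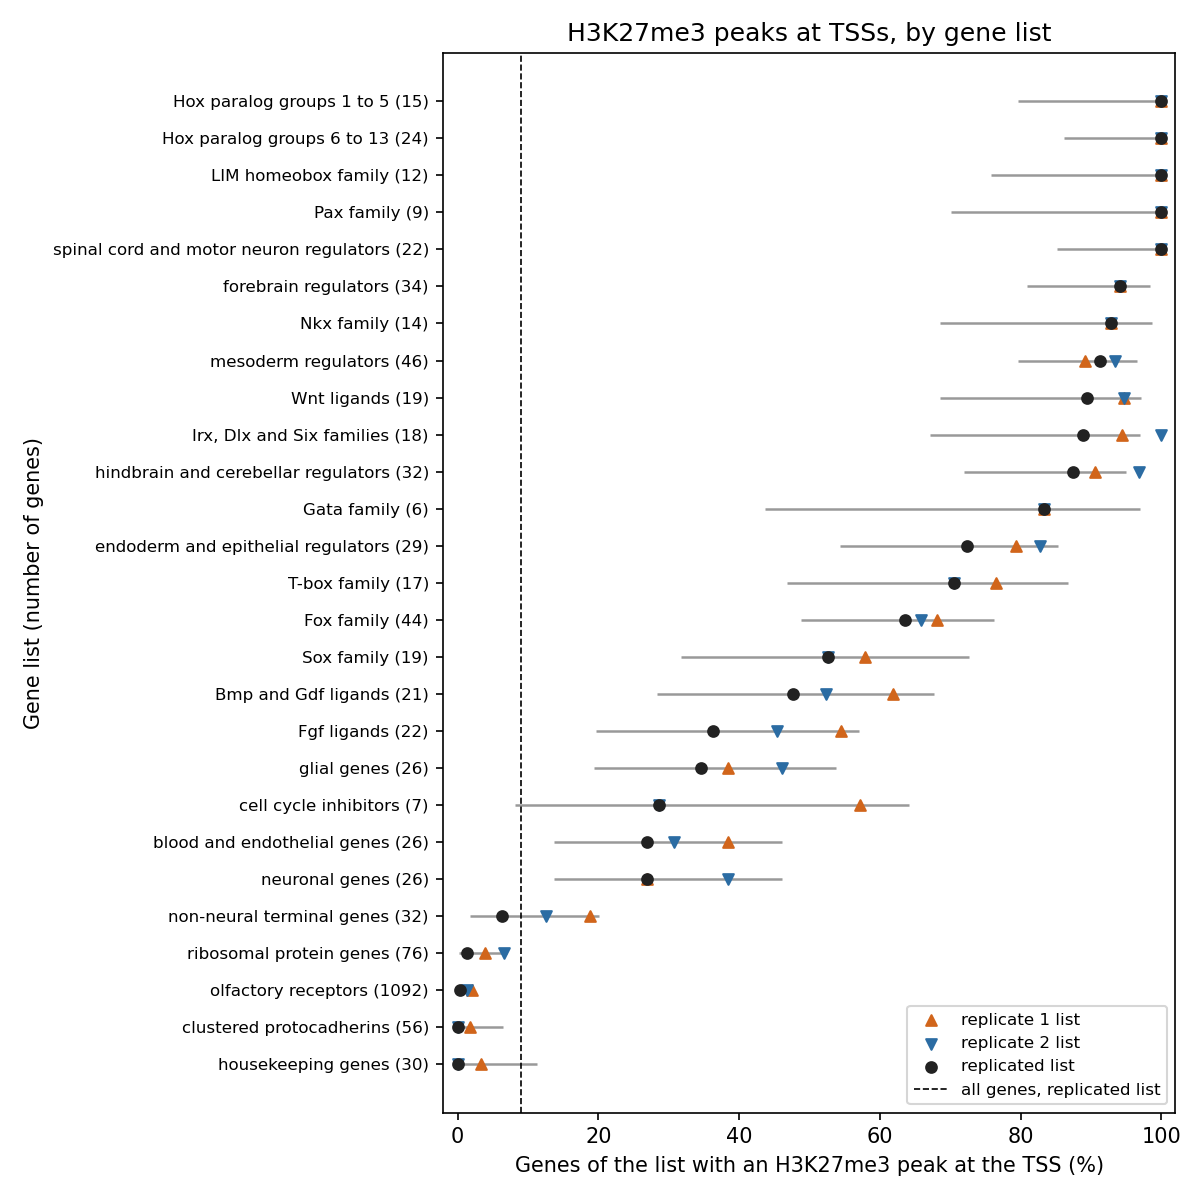
Percent of the genes of each list with an H3K27me3 peak at the TSS (horizontal axis) for 27 gene lists (vertical axis, number of genes in parentheses); circles are the replicated list with Wilson 95% intervals as lines, triangles the lists of replicates 1 and 2, and the dashed line is the 9.05% of all genes. The 5 regulator lists lie between 72.4% and 100% in the replicated list.

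The Hox genes, which set position along the body axis, lay under the longest stretches of H3K27me3, and those of paralog groups 6 to 13 were covered more fully than those of groups 1 to 5. Gene bodies of the 24 genes of groups 6 to 13 were covered to 93.3% ± 9.60 (SD over genes) and those of the 15 genes of groups 1 to 5 to 78.7% ± 13.9. The difference was 14.6 percentage points (95% interval 6.92 to 22.3, permutation p = 0.00036). It was 18.4 points in the replicate 1 list and 16.3 points in the replicate 2 list. Paralog group 2 was the least covered, with Hoxa2 at 54.0% and Hoxb2 at 55.9%, while Hoxc11 and Hoxb13 were covered to 100%. Coverage was not graded throughout: Hoxa13, in the most posterior group, had 53.3%, and Hoxa1 had 97.0%. By cluster, replicated peaks covered 93.9% of the Hoxc span, 85.0% of Hoxd, 84.3% of Hoxa and 68.5% of Hoxb, where one domain ended at 96210827 and the next long one began at 96246407, between Hoxb13 and Hoxb9. Each replicate list covered less of every cluster, with 70.8% and 86.1% of the Hoxc span in the lists of replicates 1 and 2. Gene models of neighbours overlap, so the 39 genes are not independent. The models of Hoxa3 and Hoxc5 run across genes of groups 6 to 13, so their covered shares are partly those of such genes. With the best peaks of replicate 2, as many as in the replicated list, the difference of 12.9 points did not pass the threshold (permutation p = 0.0832).

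**Figure D2:**
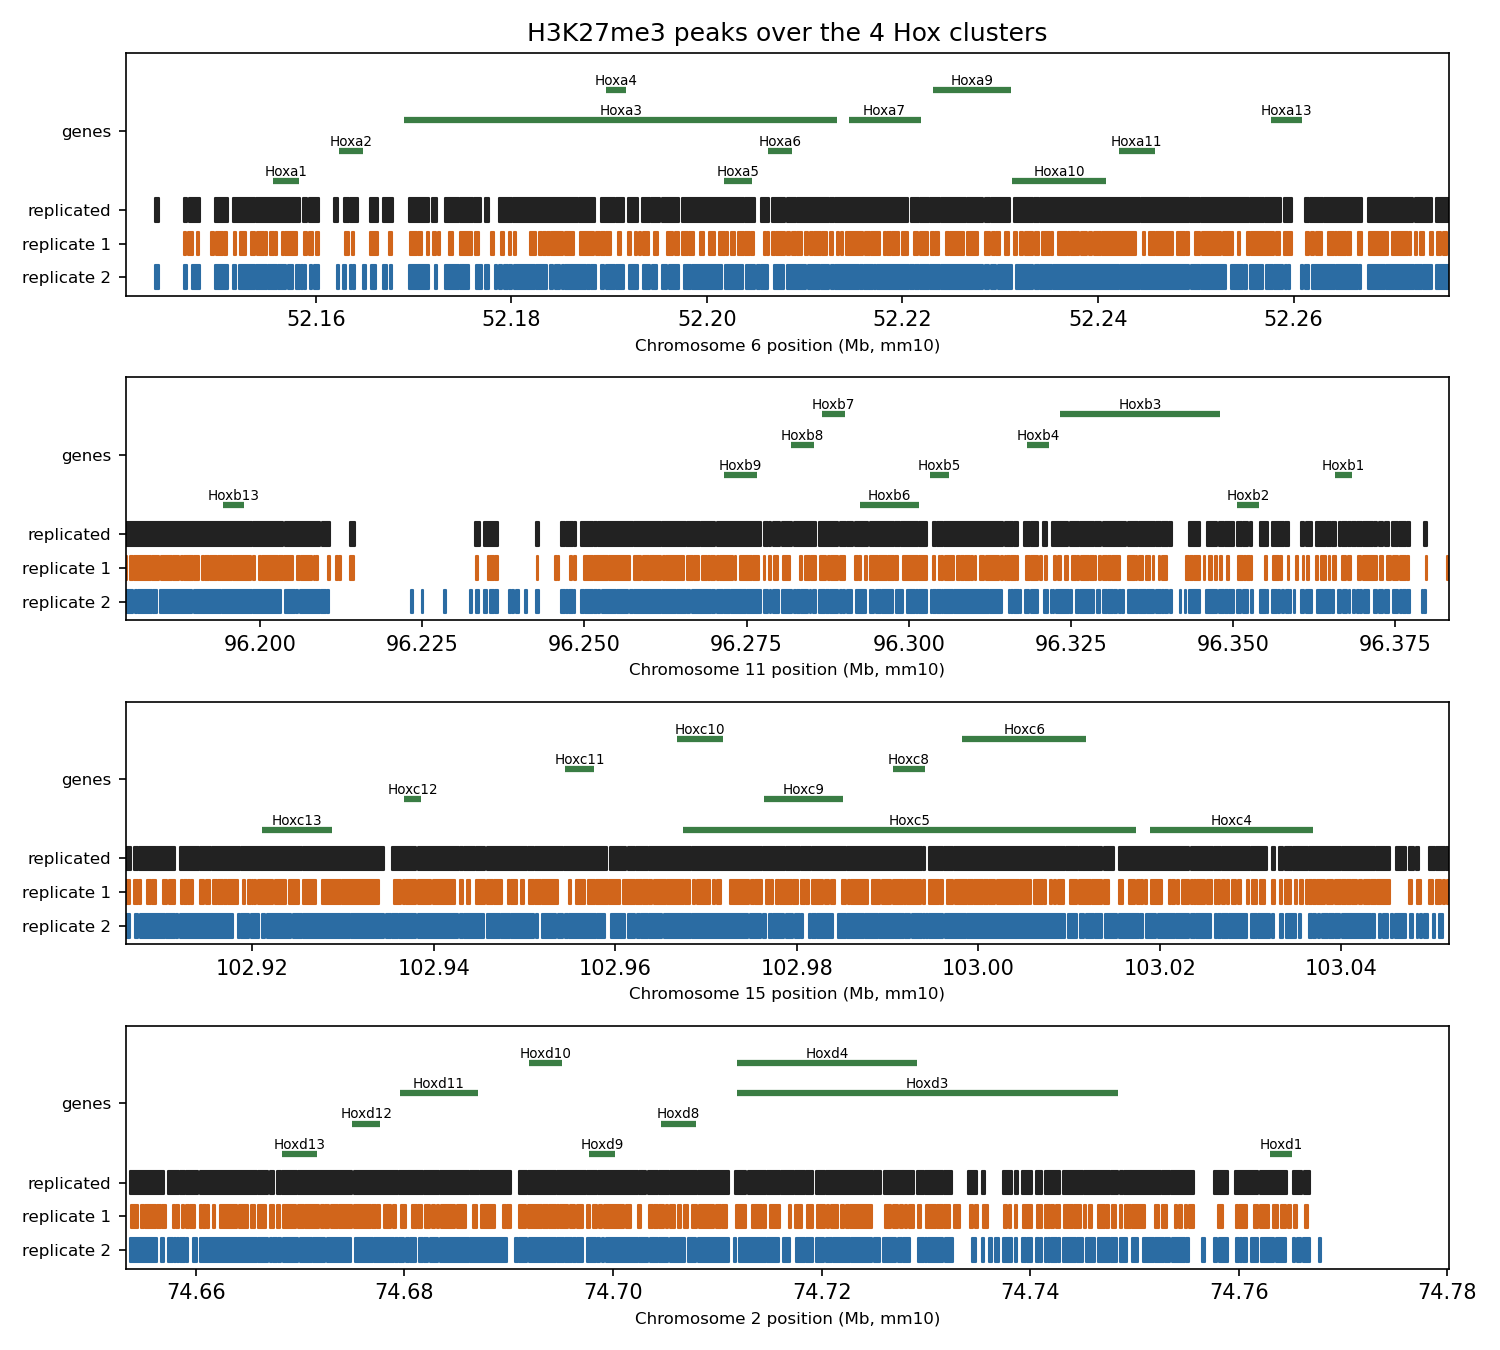
Peaks of the replicated list and of the lists of replicates 1 and 2 (bars) below the gene models (lines) over the 4 Hox clusters, with position in Mb on mm10 on the horizontal axis of each panel. Peaks run through the Hoxc cluster (93.9% of its span), and Hoxb shows sparse peaks between the domains around Hoxb13 and Hoxb9 (68.5% of its span).

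A further question was whether regulators of the tissue itself differed from those of another brain region. TSS windows of the 34 forebrain regulators were covered to 74.1% ± 23.9 (SD over genes) and those of the 32 hindbrain and cerebellar regulators to 53.4% ± 30.8. The difference of 20.7 percentage points had a 95% interval of 7.80 to 34.1 (permutation p = 0.00312). It was 13.1 points in the replicate 1 list (permutation p = 0.015) and 17.1 points in the replicate 2 list (permutation p = 0.00443). In the replicated list the least covered hindbrain genes were Meis1, Meis2, Zic2 and Zic4 at 0% and Zic1 at 5.28%, and without these 5 genes the difference was 11.03 points (permutation p = 0.0716). Leaving out the lowest genes of 1 list shrinks the difference by construction. Without the 5 least covered genes of each list it was 18.95 points, a trim by outcome that also narrows the spread, so its p is not read. How often the lists carried any peak was not shown to differ, at 32 of 34 against 28 of 32 (Fisher's exact p = 0.42), and the sign of that difference changed in the replicate 2 list, where 32 of 34 and 31 of 32 were marked. A mean share near that of the hindbrain list was not particular to regulators of the tissue itself. In the replicated list endoderm and epithelial regulators were covered to 54.9% ± 39.4, mesoderm regulators to 68.2% and spinal cord and motor neuron regulators to 75.6%.

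**Figure D3:**
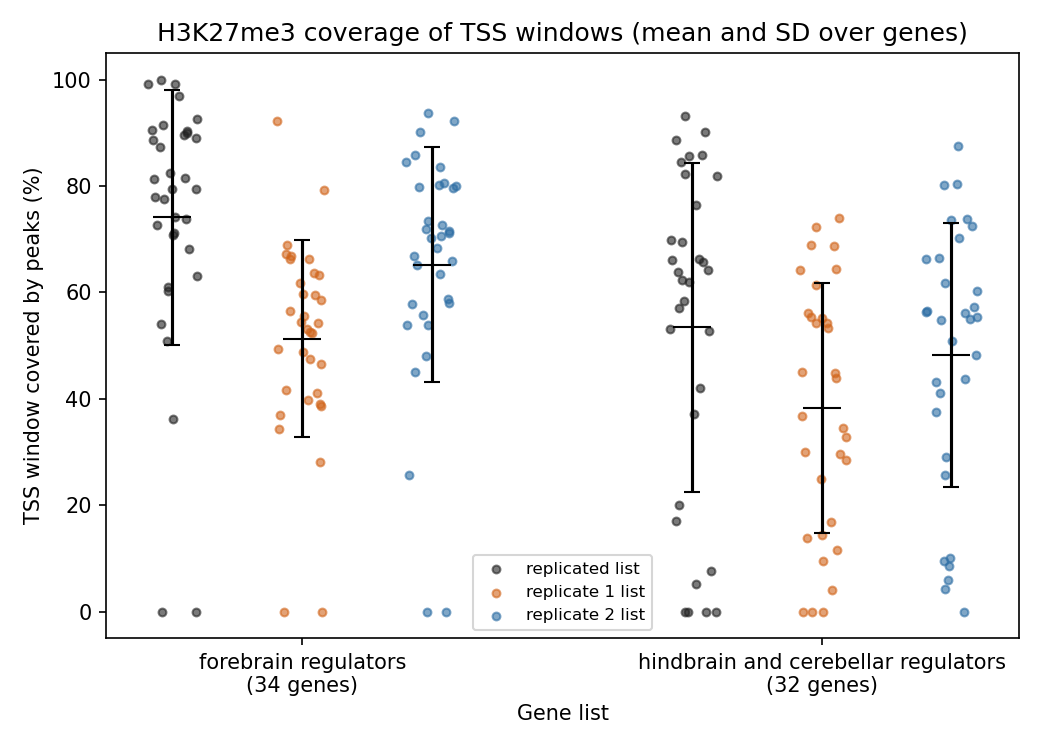
Percent of the TSS window under H3K27me3 peaks (vertical axis) for each gene (points) of the forebrain list (34 genes) and of the hindbrain and cerebellar list (32 genes), in the replicated, replicate 1 and replicate 2 lists; bars are the mean and SD over genes. Means in the replicated list were 74.1% and 53.4%.

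Replicated peaks were concentrated around TSSs. TSS windows held 32.5% of replicated peak bases, against a mean of 4.22% over 100 shifts of the peaks (7.70-fold, permutation p = 0.01, the smallest these shifts can give). Other exons held 6.499% (1.955-fold), whereas introns held 22.5% (0.617-fold) and intergenic sequence 38.5% (0.688-fold). In the single replicate lists TSS windows held 21.6% and 23.3% of peak bases. Peaks were richer in CpG than random intervals of the same width, with a median observed/expected ratio of 0.260 against 0.159, and 10.8% of peaks were above a ratio of 0.6 against 1.17% of random intervals. The median was 0.357 for the 4105 peaks at TSS windows and 0.229 for the 7982 elsewhere.

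Chromosome X differed between the replicates. In the replicate 1 list X held 7193 bp of peaks per Mb, the third highest density of 20 chromosomes, and in the replicate 2 list 1628 bp per Mb, the lowest. X carried 4568 peaks in replicate 1 and 1095 in replicate 2. The ratio of replicate 1 to replicate 2 peak bases was 4.42 on X and between 0.767 and 0.863 on the 19 autosomes. The replicated list, with 1112 bp per Mb, had the lowest density on X as well, 0.264 times the autosomal median (log2 −1.92), while the log2 value was 0.57 in the replicate 1 list. The density on X is thus decided by which replicate is read, and no direction is drawn for X.

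**Figure D4:**
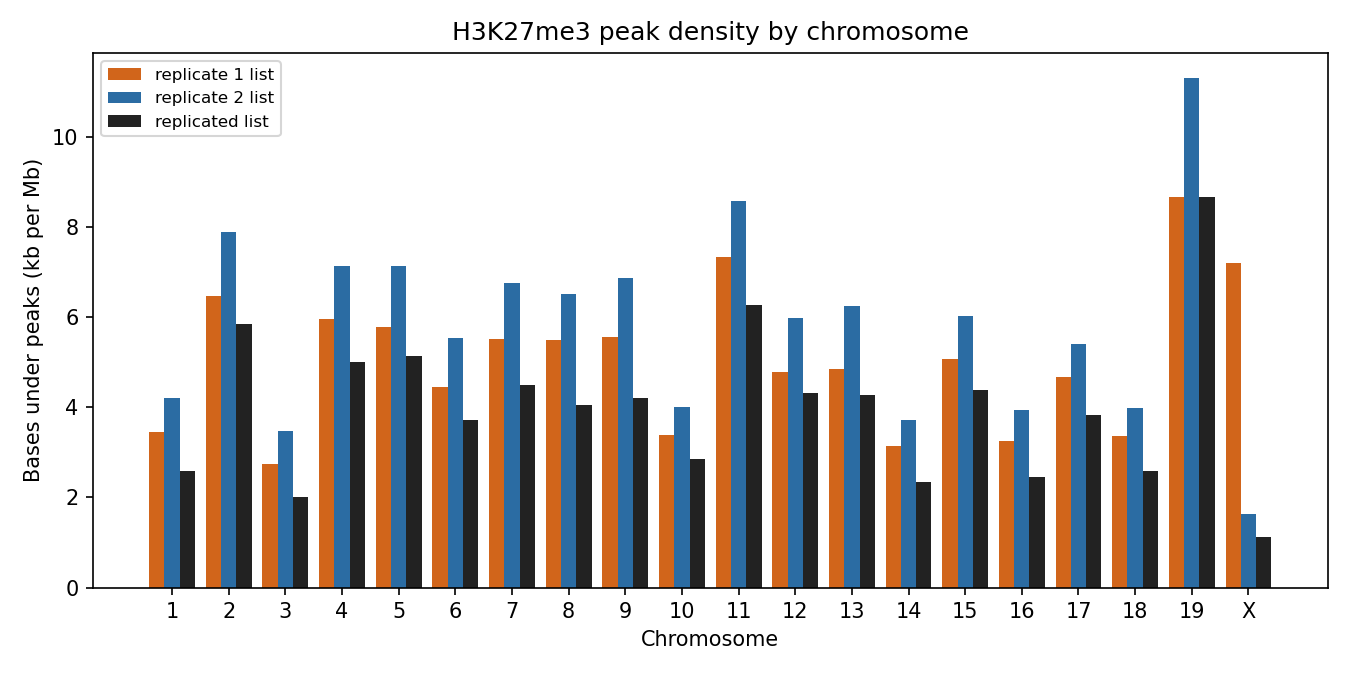
Bases under H3K27me3 peaks in kb per Mb (vertical axis) for each chromosome (horizontal axis) in the replicate 1, replicate 2 and replicated lists (bars). On the 19 autosomes the replicate 1 bars are 0.767 to 0.863 times the replicate 2 bars, and on X 4.42 times.

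Replicated peaks merged into 4791 domains, with a median of 662 bp, of which 316 spanned at least 10 kb and 126 at least 20 kb. Of the 316, 241 (76.3%) contained a protein-coding TSS. The longest lay over the Hox clusters: 186 kb over Hoxa with Evx1 (chromosome 6, 52143591 to 52329898), 162 kb over Hoxc, 134 kb over Hoxb1 to Hoxb9 and 123 kb over Hoxd with Evx2. The fifth, of 69.6 kb on chromosome 7 (49656392 to 49725943), overlapped no annotated gene. The others lay over Tfap2a, a neural crest factor (49.5 kb, chromosome 13), Cdkn2a and Cdkn2b (49.5 kb, chromosome 4), Hoxb13 and Ttll6 (47.5 kb), Nkx2-1, a ventral forebrain and lung factor (47.1 kb, chromosome 12), and Hand2, a heart and sympathetic neuron factor (46.4 kb, chromosome 8). Of these 10 domains, 6 were touched by the 10 longest of the replicate 2 list alone and 7 by those of the replicate 1 list alone.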

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

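Alternatives using any transcript start, a background without chromosome Y, the TSS window in place of the Hox gene body, or lists without their least covered genes were chosen after the data were seen. Of 485 alternatives, 440 were rated the same and 25 moved. Another 7 fell short of a threshold passed before, 5 passed one missed before and 8 changed sign. The rating depended on the kind of result. Tested differences had to keep direction and side of the threshold, and counts to stay within a fixed fold. Overlap and TSS shares had to stay above the shifts. CpG ratio, X density and domain length could move by the SD between the replicate lists. Rank agreement and the kept share of pooled peaks had to stay within an interval around the main value. Where no reason is given below, the cause was not tested. No paired analysis was possible because there was 1 group. Read depth was not known, so what it limits could not be worked out.

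Stricter thresholds leave fewer peaks by construction: at −log10 q of at least 2, 6574 (replicate 1), 13921 (replicate 2) and 24412 (pooled), and at −log10 p of at least 5, 10942, 14047 and 22919. The share of replicate 1 peaks overlapped by replicate 2, 32.9%, was 63.1% and 49.6% at these thresholds, 46.8% for the 10000 best peaks of each, and 27.2% and 13.5% when 50% of the shorter or of both peaks had to overlap. The Jaccard index, 0.195, was 0.253 and 0.267 at the thresholds and 0.279 for the best peaks. The rank agreement of the replicates was 0.44 with −log10 p in place of the signal and 0.38 at −log10 q of at least 2. Genes with a TSS peak numbered 3447 to 3451 with one replicate left out and 4287 with the pooled list. The median CpG ratio was 0.266 at −log10 p of at least 5, 0.204 to 0.212 with one replicate left out, 0.243 and 0.250 for the best peaks of replicates 1 and 2, and 0.2 for pooled peaks. The longest domain was 165 kb at −log10 p of at least 5, 172 to 188 kb with one replicate left out, 116 and 162 kb for the best peaks of replicates 1 and 2, 199 kb for pooled peaks and 147 kb at a merge distance of 1 kb. Of the 10 longest domains, 6 to 7 were touched by the 10 longest with one replicate left out, and 6 at 1 kb.

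Differences between a list and other genes, in percentage points, ranged with one replicate left out from 15.0 to 22.8 for blood and endothelial genes, 11.2 to 22.7 for neuronal genes, −15.8 to −12.4 for housekeeping genes, 12.8 to 41.4 for cell cycle inhibitors and −3.25 to 3.02 for non-neural terminal genes. Without replicate 1 the blood call was lost and housekeeping genes passed as lower, and without replicate 2 the neuronal call was lost and cell cycle inhibitors passed as higher. With pooled peaks the differences were 15.1 for blood and endothelial genes (call lost), −16.3 for housekeeping genes (passed) and 2.31 for non-neural terminal genes. Non-neural terminal genes also changed sign with the best peaks of replicate 2 (1.5) and among genes in the upper part (above the median) of CpG ratio (53.4), where few members remain. Cell cycle inhibitors also passed the threshold with the best peaks of replicate 1 (35.0) and with a window of 5 kb (32.6). Ribosomal protein genes no longer passed with a window of 1 kb (−5.67), nor olfactory receptors among genes in the upper part (above the median) of CpG ratio (−13.3). The Hox difference was 12.9 points with the best peaks of replicate 2 and no longer passed. The regional difference was 11.03 points without the 5 least covered hindbrain and cerebellar genes, a choice that lowers it by construction. The share of forebrain minus hindbrain regulators with any peak was −2.76 to 3.49 points with one replicate left out and −2.76 with pooled peaks and with a window of 5 kb. The log2 density of X against autosomes was −1.89 to 0.57 with one replicate left out.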

Other observations

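The gene families below, the test of sensitivity between the replicate lists, the ratio on X without its fullest bins, and the regional difference with both lists trimmed were chosen after the results were seen. Protein-coding genes outside the 27 lists were grouped by the letters that open their symbols, and 239 groups of at least 10 genes were tested with Fisher's exact test and Benjamini-Hochberg adjustment. These groups were not set against random lists matched on CpG, so their calls, higher or lower, are not separated from CpG content. Symbols starting with Col, mostly collagens, carried TSS peaks at 18 of 45 genes (40.0% against 8.98% of other genes, adjusted exact p = 2.88e-06), and 25 and 23 were marked in the lists of replicates 1 and 2. Among them were Col13a1, with 78.8% of its window covered, Col15a1 with 66.8%, and Col2a1, the main collagen of cartilage, with 56.7%, whereas Col3a1 had no peak. Several collagens share a promoter: Col4a1 and Col4a2 had the same 22.3%.

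The tandem-pore potassium channels (Kcnk) had a peak at 7 of 14 genes (adjusted exact p = 0.00568), led by Kcnk15 (91.0% covered), Kcnk12 (80.3%) and Kcnk9 (68.5%). Serotonin receptors (Htr) had a peak at 6 of 14 (adjusted exact p = 0.0412), with Htr6 at 65.6% and Htr1a at 38.0%. Lower than other genes were the vomeronasal receptors (Vmn), with 0 of 330 (adjusted exact p = 8.58e-12), and the zinc finger genes named Zfp, with 11 of 394 (2.79%, adjusted exact p = 6.69e-05). The lists of replicates 1 and 2 marked 9 and 10 Kcnk genes, 10 and 11 Htr genes, 1 and 0 Vmn genes, and 26 and 21 Zfp genes. In the replicated list these 4 groups and Col were the only groups of the 239 to pass the threshold.

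The difference between the replicates in peak bases on chromosome X was weighed against technical explanations. In replicate 1 the density on X, 7193 bp per Mb, lay inside the range of the autosomes (2751 to 8663). In replicate 2 it was 1628 bp per Mb, below the lowest autosome (3484). Which replicate departs was not tested, and the bin values below use bases found in replicate 1 alone. A general difference in sensitivity predicts similar ratios on all chromosomes, but X had 4.42 against at most 0.863 on autosomes. With both lists reduced to their 10000 best peaks the X ratio was 6.29, which argues against weak calls as the whole cause. X held 720 and 101 of these peaks in replicates 1 and 2, against 10.7% and 2.56% of all peaks. Its share thus fell in both lists, and the rise of the ratio is not read. The 5 fullest 1 Mb bins held 26.9% of the X bases found in replicate 1 alone, and the ratio without them was 4.40, which argues against a few regions. Over 1 Mb bins of X those bases had a Spearman rho of 0.42 with the number of protein-coding TSSs, inside the range of 0.08 to 0.67 of the autosomes, so a different dose of X relative to the control and H3K27me3 on the inactive X cannot be told apart. Both pools are labelled as mixed in sex, and a different share of females may be a candidate explanation that the labels leave open.

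The higher coverage of forebrain than hindbrain and cerebellar regulators was also weighed. Within 3 strata of CpG observed/expected the difference was 18.9 percentage points (permutation p = 0.0074), and it was 13.1 points in the replicate with the smaller difference, which argues against CpG content and against 1 replicate alone as the whole cause. Whether a few hindbrain genes with little coverage account for it stays open. Without the 5 least covered (Meis1, Meis2, Zic1, Zic2 and Zic4) the difference was 11.03 points (permutation p = 0.0716). That test lowers the difference by construction, since it trims 1 list by its outcome, and with the 5 least covered genes of each list left out the difference was 18.95 points, without a p that can be read because this trim also follows the outcome and narrows the spread.

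The frequent marking of developmental regulators was set against 2 technical explanations. Of the 163 genes of the 5 regulator lists 89.0% had a TSS peak, against a median of 11.7% and a highest value of 20.9% over 10000 lists matched on CpG content. With 1 gene kept per domain the share was 88.4% against 7.66% of other genes (Fisher's exact p = 7.13e-129). Both values argue against CpG content and shared domains as the cause, and no biological explanation was tested because the design has 1 group.

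The 3 strongest −log10 p values in each of the 4 lists were not at developmental genes. These loci were named after their values were seen. In the pooled list the strongest lay at chromosome 17, 39847876 to 39848906, over Gm42418 and AY036118, with a −log10 p of 89.9 but a signal of 2.47. The next was at chromosome 5, 146261004 to 146261481, inside Cdk8, with 70.9 and a signal of 4.62. Chromosome 17, 39843015 to 39846782, over Gm26917, followed with 67.3 and a signal of 2.18. Among replicated peaks the chromosome 17 signals lay at percentiles 3.08 and 0.786, and that of Cdk8 at 86.3. The −log10 p of the chromosome 17 peaks is thus not read as strong enrichment. No conclusion is drawn from the Cdk8 peak either. In the pooled list its −log10 p exceeded the 31.8 of a chromosome 15 peak with a higher signal of 8.59. Regions prone to artefacts were not filtered out here.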
